A study of Drosophila melanogaster with 8 samples.

How the data were processed

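Hearts of adult Drosophila melanogaster, female per the labels, were profiled on 8 Affymetrix GeneChip arrays, 2 in each of 4 groups. The groups combine the cross with the age: GMH5 crossed to yw, called control here, or GMH5 crossed to FOXO, at 1 week or at 5 weeks. GMH5 is a fly line that switches on transgenes in the heart, and FOXO is the transcription factor that acts downstream of insulin signalling. Per the labels, fat and pericardial cells were taken off the exposed heart tubes by suction, and the RNA was amplified before labelling with biotin.

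The values used are those deposited by the authors, on the log2 scale, with 1 value per probe set after summarisation and normalization between arrays. The methods of both steps are not given in the sources used here. The submitters' processing notes name limma, without a version. The log2 unit was read from the values, which lay between 2.14 and 14.5, with array means between 6.84 and 6.88. The number of arrays limits the precision of each value. The labels do not say whether the replicates came from separate flies, so the p-values measure only the spread between these samples, which may be technical.

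Of 18952 probe sets, 183 were array controls and the other 18769 were tested. Of these, 13647 carried 1 gene symbol, 402 carried several and 4720 carried none, and 13544 of the single symbols were found in the current reference table. Genes were represented by the probe set with the highest mean over all arrays, which gave 11982 genes. Probe sets without a single symbol were counted but not named.

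Tests were run in R 4.3.3 with limma 3.58.1. A model with 1 mean per group and 4 residual degrees of freedom gave 5 contrasts: FOXO against control at each age, 5 weeks against 1 week in each cross, and the difference of the FOXO effect between the ages. A second model, genotype plus age with 5 residual degrees of freedom, gave FOXO against control over both ages and 5 weeks against 1 week over both genotypes. It takes a difference of the FOXO effect between the ages as part of the spread, which can lower its counts. The moderated test of limma was two-sided, and probe sets with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed.

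For 31 gene lists (protein quality control, metabolism, muscle, immunity and markers of other cell types), camera of limma was run with its preset correlation of 0.01. Its p-values were adjusted over 155 list tests of the first 5 contrasts and over 62 of the other 2. Each was run again with an estimated correlation and with fry, which tests whether a list moves on balance in 1 direction and does not compare it with other genes. The members that passed the test of single genes were also counted with p-values adjusted over the list alone.

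The genes named per comparison were the 10 with the largest rise and the 10 with the largest fall among probe sets with 1 symbol that passed the test and whose groups did not overlap. For the difference of effects 5 per direction were named. Where fewer than 5 passed in a direction, the 5 with the smallest p were given as values. To these were added foxo and, from each list described, up to 4 members with the smallest p.

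The groups, comparisons, tests, lists and the rule for named genes were chosen before the data were examined. So were these alternatives: quantile normalization, centring of the array medians, leaving out the dimmest 40% of probe sets, eBayes with trend and robust, arrayWeights, 1 probe set per gene, a replicate block, an adjusted p under 0.1, only the 4 arrays of the compared groups, the average of 2 contrasts for the comparisons over both, and each array left out in turn. Chosen after seeing the data were the marker covariates, the count without probe sets that follow a marker list, the fit of 6 arrays without the FOXO 1 week group, and 8 further marker lists of germline and sex-specific transcripts.

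The procedure was tested on simulated data with the observed spread of each probe set, taken as equal in all groups. The FOXO 1 week replicates varied more than the others. Recovery can therefore be too high for contrasts with that group and too low for the rest. Of 100 probe sets changed by 2 on the log2 scale, between 70% and 87% were recovered in the 4 comparisons of pairs of groups and 48% in the difference of effects. Of 100 changed by 1, between 30% and 35% were recovered in the pairs of groups and 3% in the difference.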

Results

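The series asks how raising FOXO in the fly heart alters its transcripts as the heart ages, with protein quality control as the theme of its title. Transcript levels were measured as log2 signal on 8 arrays: 2 for control hearts at 1 week, 2 for control hearts at 5 weeks, and 2 each for hearts labelled FOXO at these ages. Group means are given with their SD (n = 2 arrays) and log2 fold changes with their standard error. The array medians lay between 6.01 and 6.39, and the highest, 6.36 and 6.39, were those of the FOXO 5 weeks arrays. Replicates correlated across probe sets at 0.997 in control 1 week, 0.996 in control 5 weeks and 0.995 in FOXO 5 weeks. The pair in FOXO 1 week correlated at 0.963, and 2235 of its probe sets, 11.9%, differed by more than 1 on the log2 scale. In the other groups 17, 44 and 93 did. The SD of the replicate difference was 0.83 in FOXO 1 week, against 0.22 in control 1 week, 0.26 in control 5 weeks and 0.30 in FOXO 5 weeks. The model with 1 mean per group shares 1 estimate of the spread. Standard errors and p-values can therefore be too small in contrasts with FOXO 1 week and too large in the others. The first principal component held 54.2% of the variance and the second 20.9%, and FOXO 1 week replicate 1 lay apart from all other arrays on the second.

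**Figure D1:**
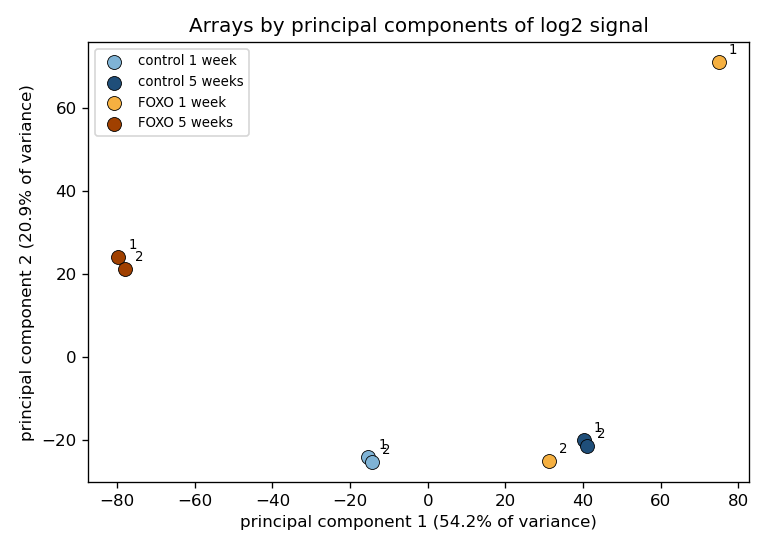
Each point is 1 of the 8 arrays, placed by its scores on the first (54.2% of the variance) and second (20.9%) principal components of the log2 values. FOXO 1 week replicate 1 lies at 70.96 on the second component, and the highest other array at 24.11.

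The foxo transcript itself did not pass the test in any comparison. Its probe set had a mean of 10.72 ± 0.05 in control and 10.66 ± 0.29 in FOXO hearts at 1 week, a log2 fold change of -0.05 ± 0.17 (adjusted p = 0.913). At 5 weeks the means were 10.38 ± 0.08 and 10.23 ± 0.02, a log2 fold change of -0.15 ± 0.17 (adjusted p = 0.653). Centring the array medians gave 0.08 at 1 week, and leaving out FOXO 1 week replicate 1 gave 0.15. Whether the probe set covers the transgene is not given in the sources used here.

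Transcripts of other cell types differed strongly between arrays, in marker lists written after the data were first seen. The 29 late spermatogenesis transcripts, such as ProtA, which packs sperm chromatin, and betaTub85D, the tubulin of the male germline, had a median of 8.38 on both control 1 week arrays and of 9.89 and 9.75 on the FOXO 5 weeks arrays. Their medians were 5.28 on both control 5 weeks arrays and 5.01 and 6.28 in FOXO 1 week. Y-linked fertility genes (7 measured) had medians of 3.71 and 3.92 in FOXO 5 weeks and at most 3.06 elsewhere, and 9 regulators of spermatocyte transcription lay between 4.66 and 5.21. The 5 female-specific transcripts of fat body and oenocytes, the yolk proteins Yp1, Yp2 and Yp3 and the pheromone enzymes Fad2 and eloF, had medians of 6.75 and 6.59 in control 1 week and 6.18 on FOXO 1 week replicate 2. On the other 5 arrays they lay between 13.03 and 13.44. Fat body and oenocyte markers without sex-specific expression lay between 12.86 and 13.16 on all 8 arrays. Oocyte and nurse cell transcripts, such as osk, which patterns the egg, had a median of 11.13 on FOXO 1 week replicate 1 and at most 4.91 elsewhere. Male accessory gland transcripts had medians of 5.85 and 5.24 in control 1 week, 5.32 on FOXO 1 week replicate 2 and at most 4.46 elsewhere, and eggshell transcripts lay between 4.70 and 5.49.

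**Figure D2:**
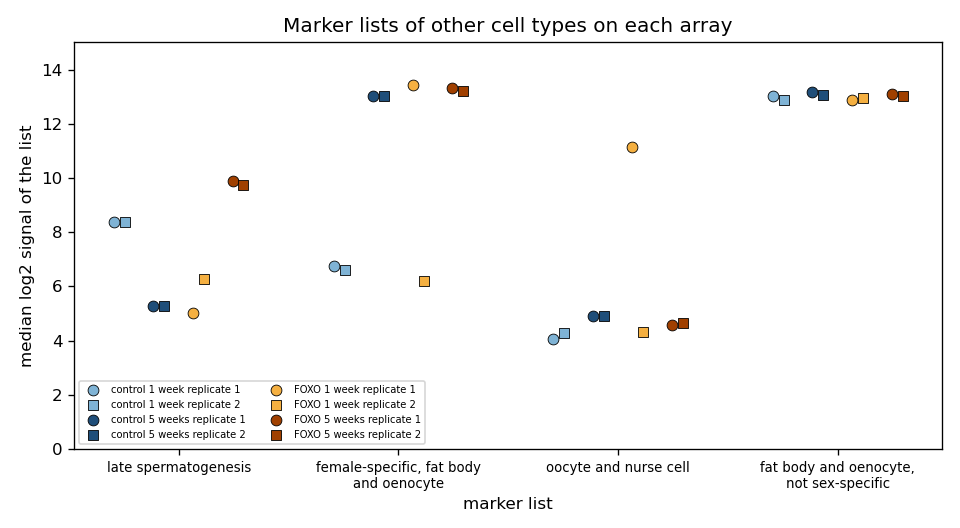
Each point is the median log2 signal of a marker list (horizontal axis) on 1 of the 8 arrays. The late spermatogenesis medians are 8.38 in control 1 week and 9.89 and 9.75 in FOXO 5 weeks, and the female-specific medians are 6.75, 6.59 and 6.18 on 3 arrays and at least 13.03 on the others.

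**Figure D3:**
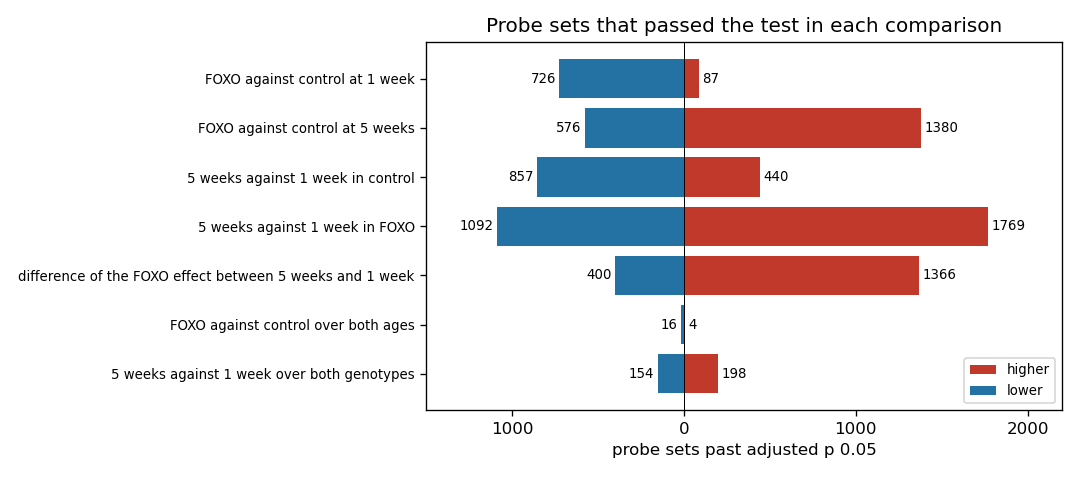
Bars give the number of probe sets past an adjusted p of 0.05 in each comparison, to the right for higher and to the left for lower signal. The FOXO effect called 87 higher and 726 lower probe sets at 1 week, and 1380 higher and 576 lower at 5 weeks.

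The first comparison asks what FOXO changed in young hearts. At 1 week the transcripts that fell most in FOXO hearts included w-cup, a gene transcribed in developing sperm, which went from 10.19 ± 0.07 in control to 5.77 ± 1.22 (log2 fold change -4.42 ± 0.49, adjusted p = 0.00278). CG14294 (-5.49 ± 0.42), CG12126 (-4.90 ± 0.22), Pif2, CG4073, CG44433, CG17666, CG32161, CG2127 and CG4836 (-4.38 ± 0.34) fell as well, with adjusted p between 0.00016 and 0.0018. Of the 29 late spermatogenesis transcripts 23 fell, and these are the transcripts with high signal in control 1 week. The largest rises were smaller: CG6034 rose by 2.41 ± 0.37 and Drsl4, a peptide of the antifungal drosomycin family, by 2.01 ± 0.32, from 8.63 ± 0.34 to 10.64 ± 0.65 (adjusted p = 0.0159). CG33640 (1.97 ± 0.26, adjusted p = 0.00614), CG14621 (1.74 ± 0.17, adjusted p = 0.0019), CG43759, BCL7-like, EbpII, CG14406, CG14062 and chas also rose.

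Among gene groups at 1 week, mitochondrial ribosome genes rose as a list by camera (adjusted p = 0.0159, and 0.996 for this list and the 2 below with an estimated correlation). The list had a median of 0.15, with 60 of 69 members positive and 0 past the test of limma for single genes or adjusted over the list alone, and mRpS31 had a value of 0.97 ± 0.25. Antioxidant and detoxification genes fell as a list (median -0.31, adjusted p = 0.0224), and 1 of 42 members fell, the glutathione S-transferase GstD10 (-1.28 ± 0.17, adjusted p = 0.00682), also 1 adjusted over the list alone. Female germline and eggshell markers rose as a list (median 0.49, mean 1.16, adjusted p = 0.0224), with 20 of 24 positive and 0 past the test, also adjusted over the list alone. The oocyte transcripts in it were high on FOXO 1 week replicate 1 alone. Without FOXO 1 week replicate 1 none of the 3 passed, with adjusted p of 0.919, 0.24 and 0.796 in the order given, and leaving out dim probe sets gave 0.116 for the germline list.

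In all, 813 of 18769 probe sets passed at 1 week, 87 higher and 726 lower, for 732 genes. Without probe sets that follow the late spermatogenesis, female-specific or oocyte lists 290 were called, 81 higher and 209 lower, a count chosen after seeing the data. The probe sets left out were picked by correlation over the same arrays, so a lower count follows from the choice. The full count was 400 without control 1 week replicate 1, 429 without control 1 week replicate 2 and 5377 without FOXO 1 week replicate 2, and 274 from the 4 arrays of the compared groups. CG6034, CG14062 and GstD10 no longer passed without either control 1 week array (largest adjusted p = 0.121, 0.187 and 0.0812). EbpII and CG14406 did not pass without control 1 week replicate 1 (adjusted p = 0.0518 and 0.0591), nor did BCL7-like, Drsl4 and chas without any 1 of the 4 control arrays (largest adjusted p = 0.171, 0.138 and 0.194).

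The second comparison asks what FOXO changed in old hearts. At 5 weeks genes of sperm formation rose most in FOXO hearts: betaTub85D went from 4.54 ± 0.06 to 10.68 ± 0.03 (log2 fold change 6.14 ± 0.26, adjusted p = 1.83e-05), ProtA from 3.88 ± 0.29 to 9.82 ± 0.10 (5.94 ± 0.39, adjusted p = 6.53e-05), and tHMG1, an HMG-box protein of the testis, rose by 6.52 ± 0.29 (adjusted p = 2e-05). CG17744, CG30039, CG31948, tHMG2, CG18449, CG9920 and the long noncoding RNA CR9284 rose by 5.86 to 6.20. Of the 29 late spermatogenesis transcripts 28 rose. The mucin gene Muc11A fell by 6.35 ± 0.65, from 11.01 ± 0.44 to 4.66 ± 0.06 (adjusted p = 0.000569). The receptor gene Ir76a (-3.87 ± 0.31, adjusted p = 0.000165), mat (-4.54 ± 0.28), CG34296, CG8012, Ag5r, CG16762, CG14280 and Scp2, a calcium-binding protein (-2.74 ± 0.36), fell too, as did cas, a zinc finger factor of the nervous system (-4.56 ± 1.05, adjusted p = 0.0369).

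In old FOXO hearts the gut and Malpighian tubule markers fell as a list, with a median of -0.49 (adjusted p = 0.0187, 0.0294 by fry, 0.327 without dim probe sets and 0.996 with an estimated correlation). Of 22 members 5 fell and 1 rose, and adjusted over the list alone 11 fell and 1 rose. The proteases Jon65Aiv (-0.78 ± 0.15, adjusted p = 0.017), epsilonTry (-0.79 ± 0.16) and Jon44E (-0.66 ± 0.14) fell, and the lysozyme LysX rose by 0.91 ± 0.19 (adjusted p = 0.0251). Jon65Aiv and epsilonTry no longer passed without any 1 of the 5 weeks arrays (largest adjusted p = 0.114 and 0.153). LysX did not pass without either control 5 weeks array or without FOXO 5 weeks replicate 2 (largest 0.166). Jon44E and cas did not pass without any 1 array of the control groups or of FOXO 5 weeks (largest 0.156 and 0.179).

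At 5 weeks 1956 probe sets passed, 1380 higher (70.6%) and 576 lower, for 1680 genes, around a median log2 fold change of -0.16. Without probe sets that follow a marker list 1281 passed, 736 higher and 545 lower. Centring the array medians, which moved the median to -0.52, gave 9573 with 13.9% higher, and quantile normalization gave 51.8% higher. The count was 4278 without either FOXO 1 week array or without both, 1152 without dim probe sets, 3342 with arrayWeights and 3380 from the 4 arrays of the compared groups.

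The next comparison asks what age changed in control hearts. From 1 to 5 weeks the mucin Muc11A rose by 6.50 ± 0.65, from 4.50 ± 0.31 to 11.01 ± 0.44 (adjusted p = 0.0013), and the cuticle protein Cpr49Ac rose by 5.04 ± 0.34 (adjusted p = 0.000296). Rises were also called for mat (adjusted p = 0.000142), Ag5r (4.66 ± 0.19), the carbonic anhydrase CAH8, CG10814, CG34296, Nazo (4.17 ± 0.43), CG4269 and eloF, an enzyme of female hydrocarbons and 1 of the 5 female-specific transcripts (4.03 ± 0.86, adjusted p = 0.0389). The falls were led by CG14294 (-5.98 ± 0.42), w-cup (-5.68 ± 0.49, from 10.19 ± 0.07 to 4.51 ± 0.14), CG8517, CG2127 (-5.44 ± 0.43), CG17666, CG44433, CG8701, CG34168, CG4073 and CG46298 (-5.10 ± 0.31). Of the 29 late spermatogenesis transcripts 24 fell.

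With age in control hearts 5 lists passed camera, each with an adjusted p = 0.996 with an estimated correlation. Genes of oxidative phosphorylation had a median of -0.33, with 57 of 58 negative (adjusted p = 1.64e-07), and 1 passed singly, ND-B12 of respiratory complex I (-0.65 ± 0.13, adjusted p = 0.0259), and 0 adjusted over the list alone. Mitochondrial ribosome genes had a median of -0.38 with 68 of 69 negative (adjusted p = 2.87e-07) and 0 past the test of limma or adjusted over the list alone. Glycolysis genes had a median of -0.30 with all 16 negative (adjusted p = 0.00284), or -0.13 with centred array medians. In glycolysis 1 gene fell, the glycogen phosphorylase Glyp (-0.71 ± 0.14, adjusted p = 0.0315), and 5 adjusted over the list alone. Genes of the endoplasmic reticulum stress response rose (median 0.42, adjusted p = 0.00146): 2 of 19 rose, Manf, a secreted stress factor (0.60 ± 0.13, adjusted p = 0.0349), and CaBP1, a protein disulfide isomerase (0.58 ± 0.13), and 5 adjusted over the list alone. Gut and Malpighian tubule markers rose (median 0.46, adjusted p = 4.6e-05, 5 of 22, and 11 adjusted over the list alone), with LysX at 2.46 ± 0.19 and the trypsin alphaTry at 2.25 ± 0.24. Of the 5 lists 1, the gut list, passed with fry (0.0152). The list of the tricarboxylic acid cycle and fatty acid oxidation had a median of -0.25 (adjusted p = 0.0505), with 1 of 21 higher and 1 lower past the test. In this comparison the 5 female-specific transcripts had a median of 6.78, and fat body markers 0.94 (adjusted p = 0.0606, 0.996 with an estimated correlation and 0.0102 by fry), while 4 of 19 male accessory gland proteins fell. Whether the lists move with a difference between the control 1 week arrays and the others, as in these markers, was not tested.

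Age in control hearts called 1297 probe sets, 440 higher (33.9%) and 857 lower, for 1125 genes. Without probe sets that follow a marker list most were higher, 425 against 262 lower of 687. This turn follows in part from the choice, since those left out include followers of the late spermatogenesis list, which fell here. With centred medians 52.6% were higher. The count was 605 and 644 without control 1 week replicate 1 or 2, 675 and 659 without control 5 weeks replicate 1 or 2, 3279 without either FOXO 1 week array or without both, 3681 with arrayWeights and 3627 from the 4 arrays of the compared groups. The single calls of eloF, ND-B12, Glyp, Manf and CaBP1 were lost without any 1 array of the control groups or of FOXO 5 weeks, with largest adjusted p of 0.218, 0.232, 0.224, 0.253 and 0.325.

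The same question was asked in FOXO hearts. From 1 to 5 weeks tHMG1 rose by 5.89 ± 0.29, from 4.37 ± 0.38 to 10.27 ± 0.24 (adjusted p = 3.36e-05), ProtA by 5.63 ± 0.39 (adjusted p = 9.17e-05), tHMG2 by 5.38 ± 0.23, and 28 of the 29 late spermatogenesis transcripts rose. The odorant-binding protein gene Obp56d rose by 5.75 ± 0.27 (adjusted p = 2.91e-05), with CG31948, CG31802, CG17744, CG32081, CG31709 and CG10734. Falls were led by the cuticle proteins Cpr49Ae (-4.85 ± 0.29, from 11.30 ± 0.61 to 6.45 ± 0.24, adjusted p = 5.04e-05), Cpr65Au (-3.67 ± 0.52) and Cpr100A (-3.21 ± 0.30), and by Drsl4 (-4.49 ± 0.32, adjusted p = 0.000105). CG7203, CG18302 and CG4000 fell, as did CBP, Esp and the oxidase gene Duox (-3.64 ± 0.78, adjusted p = 0.023), whose SD in FOXO 1 week was 2.02.

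Mitochondrial ribosome genes fell with age in FOXO hearts too, with a median of -0.45 (adjusted p = 5.94e-06, and 0.996 for this list and the 2 below with an estimated correlation): 7 of 69 fell, among them mRpL17 (-0.75 ± 0.15, adjusted p = 0.0152), mRpS17, mRpL11 and mRpL23 (-1.10 ± 0.26), and 0 adjusted over the list alone. Genes of calcium handling and ion channels fell (median -0.51, adjusted p = 0.0224): 3 of 30 fell, the sodium-calcium exchanger Calx (-1.62 ± 0.30, adjusted p = 0.0109) and the potassium channels Irk1 (-0.71 ± 0.17) and SK (-0.70 ± 0.17), and 8 adjusted over the list alone. Female germline and eggshell markers fell (median -0.63, mean -1.26, adjusted p = 0.0224): 3 of 24 fell, the vitelline membrane gene Vm26Aa (-1.34 ± 0.31) and the chorion genes Cp38 and Cp36, and 0 adjusted over the list alone. The calcium list did not pass without FOXO 1 week replicate 2 (0.254) or FOXO 5 weeks replicate 2 (0.108), nor the germline list without FOXO 1 week replicate 1 (0.409), without FOXO 5 weeks replicate 2 (0.063) or without dim probe sets (0.116). The 3' minus 5' signal of 3 control genes was 1.13 and 0.957 in FOXO 1 week and 1.55 and 1.40 in FOXO 5 weeks, and whether it bears on these lists was not tested.

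Age in FOXO hearts called 2861 probe sets, 1769 higher (61.8%) and 1092 lower, for 2371 genes. With centred medians, which moved the median from -0.15 to -0.49, 9415 passed with 16.7% higher. The count was 4482 and 6698 without FOXO 1 week replicate 1 or 2, 1704 and 1670 without FOXO 5 weeks replicate 1 or 2, 1865 without dim probe sets, 1755 with arrayWeights, 4409 at an adjusted p under 0.1 and 1421 from the 4 arrays of the compared groups. Calx was lost without FOXO 5 weeks replicate 2 (adjusted p = 0.0741) and mRpL17 without either FOXO 5 weeks array (largest 0.0901). Losses followed for mRpS17 and SK without any 1 array of control 1 week or FOXO 5 weeks (largest 0.106 and 0.17), and for CBP without any 1 of the 5 weeks arrays (0.118). For mRpL23, Vm26Aa, Duox and Esp they followed without any 1 array of the control groups or of FOXO 5 weeks (0.162, 0.149, 0.123 and 0.154), and for mRpL11 the same but for FOXO 5 weeks replicate 2 (0.143). Irk1, Cp38 and Cp36 were lost without any 1 array but FOXO 1 week replicate 2 (0.164, 0.162 and 0.172).

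Whether the FOXO effect differed between ages was tested directly. CG14294 was lower in FOXO hearts at 1 week and higher at 5 weeks, a difference of 10.41 ± 0.59 (adjusted p = 3.62e-05), and CG2127 (9.86 ± 0.61), CG8517 (9.69 ± 0.56), CG18449 (9.65 ± 0.36) and CG3330 (9.58 ± 0.62) changed in this direction too. Of the 29 late spermatogenesis transcripts 28 did. The opposite difference was called for Muc11A (-7.84 ± 0.92, adjusted p = 0.00128), mat (-4.67 ± 0.40), Ag5r (-4.30 ± 0.27), CG34296 (-4.06 ± 0.31) and Pvf1, a growth factor of the PDGF and VEGF family (-3.57 ± 0.82, adjusted p = 0.0396), which was lost without any 1 array of the control groups or of FOXO 5 weeks (largest adjusted p = 0.156). In all 1766 probe sets passed, 1366 higher (77.4%) and 400 lower, and 1061, 714 higher and 347 lower, without probe sets that follow a marker list. At an unadjusted p under 0.05 there were 4276. Of the 31 gene lists 0 passed by camera and 0 with an estimated correlation (adjusted p = 0.996 each), and fry called 2, heat shock proteins and chaperones higher and fat body markers lower. Centred medians gave 8997 with 14.6% higher around a median of -0.72, against -0.22, quantile normalization 57.7% higher, the bright probe sets alone 1082, and the fits without FOXO 1 week replicate 1 or 2 gave 3178 and 5541.

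**Figure D4:**
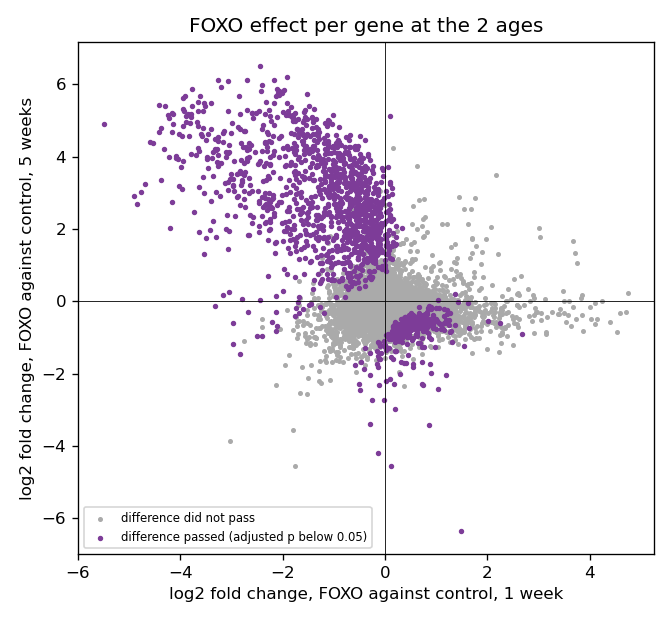
Each point is a gene, with its log2 fold change of FOXO against control at 1 week (horizontal) and at 5 weeks (vertical), coloured where the difference of the effects passed. Genes that were lower at 1 week and higher at 5 weeks fill the upper left, with 536 called both ways.

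Genes of protein quality control, the theme of the title, showed single members that moved with the late spermatogenesis transcripts. Atg8b, an autophagy gene with a role in the male germline, fell by 1.73 ± 0.22 in FOXO hearts at 1 week and rose by 4.77 ± 0.22 at 5 weeks (adjusted p = 2.25e-05). Hsp60B, a chaperonin needed in sperm formation, fell by 1.83 ± 0.19 and rose by 4.65 ± 0.19 (adjusted p = 1.79e-05), and Vha68-3, a subunit of the vacuolar proton pump, fell by 1.22 ± 0.19 and rose by 3.94 ± 0.19 (adjusted p = 2.54e-05). These were the members past the test in their lists for both FOXO effects: 1 of 29 autophagy genes, 1 of 24 heat shock proteins and chaperones and 1 of 30 lysosome and V-ATPase genes, also adjusted over the list alone. The differences of the effects passed for all 3: 6.49 ± 0.32, 6.48 ± 0.26 and 5.15 ± 0.27. Among FOXO targets known from other fly tissues daw, an activin-like ligand, fell by 0.68 ± 0.14 at 1 week (adjusted p = 0.0459) and rose by 0.80 ± 0.14 at 5 weeks (adjusted p = 0.011), 1 of 16 genes each time and also adjusted over the list alone, and the difference was 1.48 ± 0.20 (adjusted p = 0.00274). The chaperone gene Hsc70-1 fell with age in control (-1.45 ± 0.20, adjusted p = 0.00541) and in FOXO hearts (-1.47 ± 0.20, adjusted p = 0.00247).

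As lists, the protein quality control groups did not pass camera for either FOXO effect. Only matched names were tested: 24 of 40 for heat shock proteins and chaperones and 16 of 23 for FOXO targets. Unmatched were all Hsp70 genes of the list, Hsp83, Hsp22 and Hsp23, and of the FOXO targets Thor, Ilp6, chrb and Rpt6, among others. The proteasome core had medians of 0.04 at 1 week (adjusted p = 0.603) and 0.04 at 5 weeks (adjusted p = 0.713), and the regulatory particle -0.01, where the test leaned upwards (adjusted p = 0.986), and 0.05. Ubiquitin genes had medians of 0.02 and -0.05, autophagy -0.18 (adjusted p = 0.486) and -0.04, where the mean was 0.10, and lysosome genes 0.10 and -0.09, where the mean was 0.03. Heat shock proteins and chaperones had -0.12 (adjusted p = 0.362) and -0.04, where the mean was 0.11, the chaperonin TRiC with prefoldin 0.32 (adjusted p = 0.0981) and -0.08, and FOXO targets -0.13 and -0.14. Endoplasmic reticulum stress genes had -0.05 and -0.17 (adjusted p = 0.652 and 0.176). In all of these adjusted p = 0.996 with an estimated correlation. By fry at 1 week lysosome and V-ATPase genes rose (0.0355) and heat shock proteins and chaperones fell (0.0477). Over both genotypes the proteasome regulatory particle rose with age (median 0.12, and 0.03 with centred array medians, adjusted p = 0.0045), with 15 of 15 members positive and 0 past the test of limma, also adjusted over the list alone, and adjusted p = 0.716 with an estimated correlation. Over both ages endoplasmic reticulum stress genes were lower in FOXO hearts by camera, as given below (adjusted p = 0.00992, and 0.716 with an estimated correlation). Atg8b and Vha68-3 at 1 week no longer passed without either control 1 week array (largest adjusted p = 0.0663 and 0.136), and Hsc70-1 in control without either control 1 week array or control 5 weeks replicate 2 (0.0604). The call of daw at 1 week was lost without any 1 array but FOXO 1 week replicate 2 (0.301) and at 5 weeks without any 1 array of the 5 weeks groups (0.0846).

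**Figure D5:**
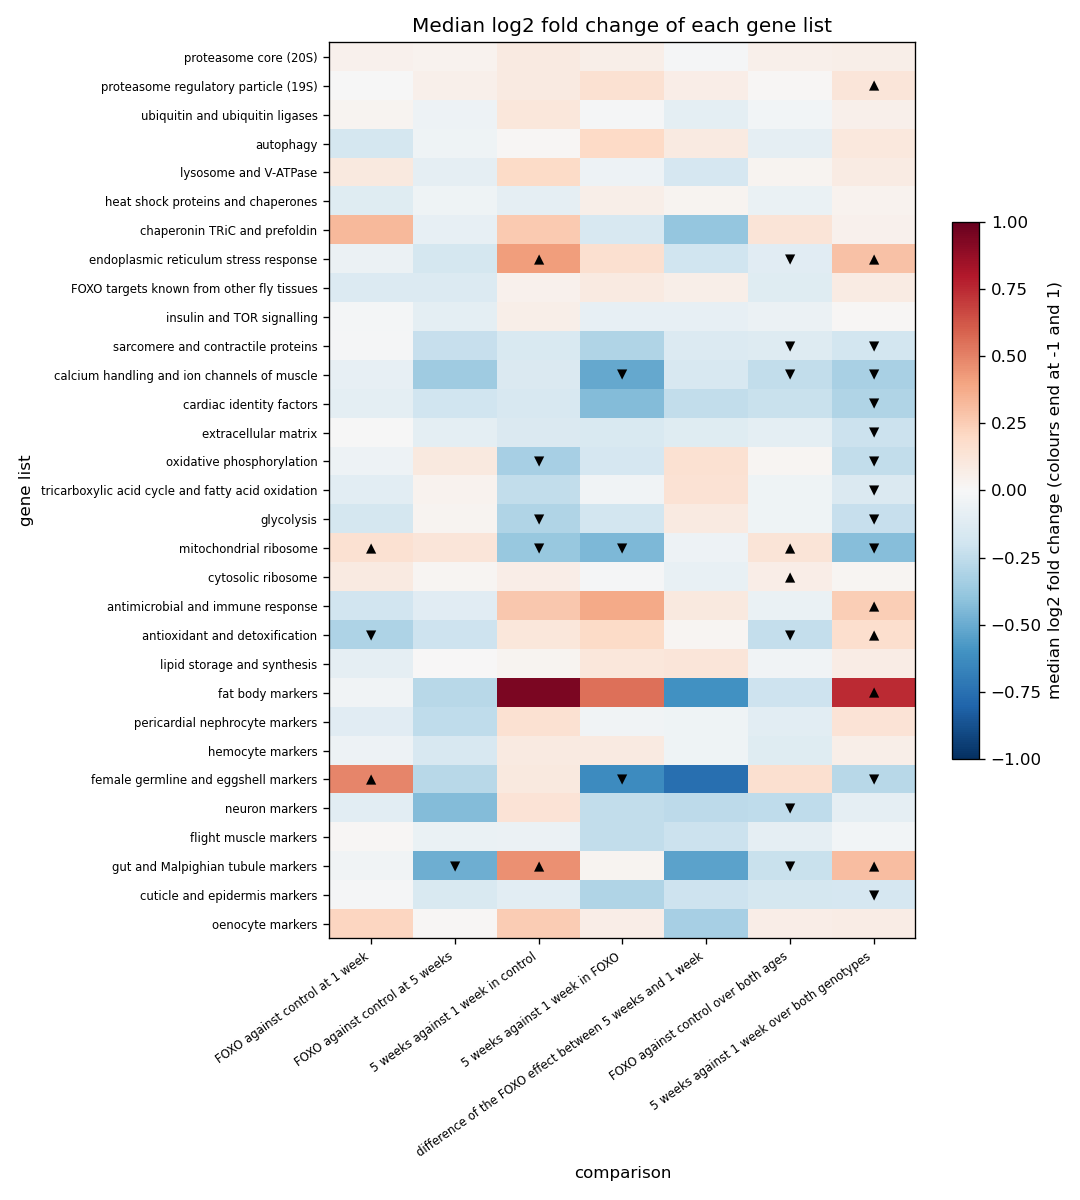
Colours give the median log2 fold change of each of the 31 gene lists (vertical) in each comparison (horizontal), and triangles mark lists past an adjusted p of 0.05 by camera, pointing in the direction of the test. The mitochondrial ribosome falls with age in control hearts (-0.38) and in FOXO hearts (-0.45).

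Over both ages, few transcripts passed between FOXO and control hearts in the model of genotype plus age. That model takes a difference of the FOXO effect between the ages as spread, so few calls do not mean few differences. CG33640 rose by 1.85 ± 0.19 (adjusted p = 0.0348), GILT3, of the lysosomal thiol reductase family, by 1.30 ± 0.15 (adjusted p = 0.049) and Ect3 by 1.06 ± 0.11 (adjusted p = 0.0348), while CG7695 and CG5056 had values of 0.87 ± 0.13 and 0.77 ± 0.12. Ir76a fell by 3.45 ± 0.27 (adjusted p = 0.0213), Rnf11, a RING finger protein, by 2.23 ± 0.25 (adjusted p = 0.049), Dh44, a diuretic neuropeptide, by 1.82 ± 0.20 (adjusted p = 0.0462) and Ugt36E1, a glycosyltransferase, by 1.60 ± 0.13 (adjusted p = 0.0218). CG14451 (-2.10 ± 0.23), CG31664, Muc68Ca, TkR99D, a tachykinin receptor, ACXD and CG10621 (-1.30 ± 0.13) fell as well. In all, 20 probe sets passed, 4 higher and 16 lower, for 17 genes. The count was 1 without any 1 array of the control groups or of FOXO 5 weeks, 19 without FOXO 1 week replicate 1 and 154 without FOXO 1 week replicate 2. It was 1168 as the average of the 2 contrasts, 142 with arrayWeights, 13 with quantile normalization, 10 with 1 probe set per gene, 7 with centred medians, 4 with trend and robust, and 1123 with marker covariates, chosen after seeing the data. A replicate block gave 1. Each of the 13 named changes was lost without any 1 of the same 6 arrays, with adjusted p up to 0.306, and CG33640, Ect3, Dh44, Muc68Ca, ACXD and CG10621 also without FOXO 1 week replicate 1.

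By camera 8 lists differed over both ages, each with an adjusted p = 0.716 with an estimated correlation. Mitochondrial ribosome genes rose (median 0.13, 66 of 69 positive, adjusted p = 1.12e-06), and so did cytosolic ribosome genes (median 0.07, adjusted p = 0.0045). With centred array medians these medians were 0.02 and -0.05. RpS5b had a value of 1.53 ± 1.37, and -0.08 without FOXO 1 week replicate 1. Antioxidant and detoxification genes fell (median -0.24, adjusted p = 5.02e-06), with the glutathione S-transferases GstD5 at -1.18 ± 0.17 and GstD10 at -1.01 ± 0.16, and 6 of 42 fell adjusted over the list alone. Genes of the sarcomere (median -0.13, adjusted p = 0.0128), calcium handling (-0.25, adjusted p = 0.00438), endoplasmic reticulum stress (-0.12, adjusted p = 0.00992, 3 of 19 adjusted over the list alone), neuron markers (-0.26, adjusted p = 0.00283, 0 adjusted over the list alone) and gut markers (-0.22, adjusted p = 0.00183, 2 of 22 adjusted over the list alone) fell. In the lists without such a count, 0 passed adjusted over the list alone. No member of these 8 lists passed over all probe sets (0 by limma, where 1594 probe sets had an unadjusted p under 0.05), and fry called 0. Without FOXO 1 week replicate 1 the lists for the cytosolic ribosome (0.343), calcium handling and ion channels of muscle (0.126), neuron markers (0.0902) and the endoplasmic reticulum stress response (0.0846) did not pass. Without FOXO 5 weeks replicate 2 the lists for sarcomere and contractile proteins (0.0574) and the stress response (0.0922) did not.

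Over both genotypes, age raised Nep2, a peptidase, by 3.42 ± 0.14, from 7.58 ± 0.15 to 11.20 ± 0.05 in control and from 7.54 ± 0.19 to 10.76 ± 0.18 in FOXO hearts (adjusted p = 0.000922). The glutathione S-transferase GstD5 rose by 3.35 ± 0.17 (adjusted p = 0.00198), with CG4269 (4.20 ± 0.26), CAH8, Nazo, CG1941, LysX (3.31 ± 0.35), Obp56d, CG10814 and CG33093. TpnC41C, a troponin C of muscle, fell by 2.01 ± 0.13 (adjusted p = 0.00371), and the cuticle protein Cpr49Ae by 3.97 ± 0.39 (adjusted p = 0.00833), with Drsl4, Cpr65Au, CG7203, CG4000, Cpr100A, Jhe, which breaks down juvenile hormone, Acp53Ea and Ugt37A3. Acp53Ea, a male accessory gland gene, had 6.54 and 6.24 in control 1 week, 5.65 on FOXO 1 week replicate 2 and at most 4.46 elsewhere. The female-specific transcripts, low on the same arrays, had a median of 5.13 in this comparison, and 3 of 19 male accessory gland proteins fell. Whether other calls move with that difference between arrays was not tested. In all, 352 probe sets passed, 198 higher (56.3%) and 154 lower, for 280 genes.

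The count over both genotypes was 57 and 68 without control 1 week replicate 1 or 2, 56 and 61 without control 5 weeks replicate 1 or 2, 79 and 86 without FOXO 5 weeks replicate 1 or 2, and 945 without FOXO 1 week replicate 1. It was 2165 as the average of the 2 contrasts, 2463 with arrayWeights, 870 at an adjusted p under 0.1, 121 with centred medians and 4393 with marker covariates, chosen after seeing the data. A replicate block gave 213. Of the 10 named rises 4 and of the 10 named falls 8 were lost in at least 1 of the 8 fits with an array left out. LysX was lost without FOXO 5 weeks replicate 1 (adjusted p = 0.0513), CG4000 without control 5 weeks replicate 1 (0.052), CG7203 without control 1 week replicate 2, control 5 weeks replicate 1 or FOXO 5 weeks replicate 2 (largest 0.0567). Cpr100A was lost without control 1 week replicate 1, either control 5 weeks array or FOXO 5 weeks replicate 1 (0.0591), and CG10814 without any 1 control array or FOXO 5 weeks replicate 2 (0.0892). Obp56d, CG33093, Drsl4, Cpr65Au, Jhe, Acp53Ea and Ugt37A3 were lost without any 1 array of the control groups or of FOXO 5 weeks (adjusted p up to 0.138), and Obp56d also without FOXO 1 week replicate 2.

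Over both genotypes the lists called with age by camera, falling here and rising below, all had an adjusted p = 0.716 with an estimated correlation. The 3' minus 5' signal of 3 control genes lay between 0.957 and 1.23 on the 1 week arrays. It was 1.46 and 1.09 in control 5 weeks and 1.55 and 1.40 in FOXO 5 weeks. Whether the lists move with this signal or with the female-specific and accessory gland transcripts was not tested. The mitochondrial ribosome had a median of -0.43 (adjusted p = 4.41e-18), with mRpL17 (-0.69 ± 0.10) past the test and 32 of 69 members adjusted over the list alone, and oxidative phosphorylation -0.24 (adjusted p = 3.04e-11), with 0 of 58 past the test of limma or adjusted over the list alone. Glycolysis fell (-0.23, adjusted p = 4.6e-05), with Glyp (-0.68 ± 0.10) and the glycogen synthase Glys (-0.54 ± 0.09) among 2 of 16 genes, and 4 adjusted over the list alone. The list of the tricarboxylic acid cycle and fatty acid oxidation fell (-0.15, adjusted p = 0.0203): Idh3a (-0.78 ± 0.10) and Idh3g (-0.87 ± 0.13) of 21 genes fell and CG4860 rose (1.02 ± 0.10), and adjusted over the list alone 3 fell and 1 rose. Sarcomere genes fell (-0.18, adjusted p = 0.00566), 2 of 29, TpnC41C and the titin-like sls (-1.01 ± 0.15), and adjusted over the list alone 6 fell and 2 rose. Mhc, Act57B, wupA, Tm1, TpnC25D and TpnC47D were not matched and so not tested in the sarcomere list in any comparison. Flight muscle markers had a median of -0.02 (adjusted p = 0.517). Calcium handling fell (-0.32, adjusted p = 0.00108), with the calcium release channel RyR (-1.05 ± 0.18) and SK (-0.71 ± 0.12) and 8 of 30 adjusted over the list alone. Cardiac identity factors fell (-0.30, adjusted p = 0.00992), with the heart factor mid (-0.95 ± 0.17), the list member bap (-0.92 ± 0.16) and 6 of 17 adjusted over the list alone. The heart factors tin and Mef2 were not matched and so not tested in this list. Extracellular matrix genes fell (-0.21, adjusted p = 0.0468), with the perlecan gene trol at -0.97 ± 0.13 and the laminin gene wb higher by 0.74 ± 0.12, and adjusted over the list alone 5 of 24 fell and 1 rose. Cuticle markers fell (-0.17, adjusted p = 0.0196) with serp (-1.04 ± 0.10) and ect (-0.83 ± 0.14) among 2 of 23 and 3 adjusted over the list alone, as did female germline markers (-0.28, adjusted p = 0.0468), 0 of 24 past the test of limma and 0 adjusted over the list alone.

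Several of these falling lists hung on single arrays. The extracellular matrix list passed only with all arrays or without FOXO 1 week replicate 1 or FOXO 5 weeks replicate 1. The other fits with an array left out gave adjusted p between 0.0525, without FOXO 5 weeks replicate 2, and 0.107, without FOXO 1 week replicate 2. Without dim probe sets it had 0.137, and female germline and eggshell markers 0.156. The list of the tricarboxylic acid cycle and fatty acid oxidation was lost without control 1 week replicate 1 or 2 (0.0894 and 0.0701), control 5 weeks replicate 1 (0.133) or FOXO 1 week replicate 2 (0.0809), and cuticle and epidermis markers without FOXO 1 week replicate 2 (0.0951). Female germline and eggshell markers were lost without FOXO 5 weeks replicate 1 or 2 (0.106 and 0.168), and without FOXO 1 week replicate 1 the direction of the test turned (0.922). Of the genes TpnC41C and serp passed in all 8 such fits, and CG4860 was lost without control 1 week replicate 1 alone (0.0545). The titin-like sls, trol, wb, ect, mRpL17, Glyp, Glys, Idh3a, Idh3g, SK, RyR, mid and bap were lost without any 1 array of the control groups or of FOXO 5 weeks, with adjusted p up to 0.164. Of these, mid was also lost without either FOXO 1 week array, and SK, RyR, bap and Glys without FOXO 1 week replicate 2.

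Among the lists that rose with age over both genotypes (adjusted p = 0.716 with an estimated correlation), endoplasmic reticulum stress genes had a median of 0.30 (adjusted p = 1.28e-05), with 19 of 19 positive, 0 past the test of limma and 6 adjusted over the list alone. Heat shock proteins and chaperones had a median of 0.03 with a test leaning downwards (adjusted p = 0.721). Antimicrobial genes rose (0.24, adjusted p = 0.00438): the peptides AttD (2.68 ± 0.29) and CecB (1.92 ± 0.30) rose, TotC (-1.88 ± 0.15) and Drsl4 (-3.22 ± 0.53) fell, and adjusted over the list alone 5 of 29 rose and 2 fell. Antioxidant genes rose (0.17, or 0.08 with centred array medians, adjusted p = 0.00422), with GstD5 and the metallothionein MtnB (1.43 ± 0.20) and, adjusted over the list alone, 8 higher and 3 lower of 42. Gut markers rose (0.31, adjusted p = 0.000613), 5 of 22 and 6 adjusted over the list alone, among them Jon65Aiii (2.18 ± 0.22) and alphaTry (1.96 ± 0.20). Fat body markers rose (0.74, adjusted p = 0.0144, and 0.0198 by fry), with Fst (2.60 ± 0.37) as 1 of 14 and 4 adjusted over the list alone. The yolk protein genes in that list were low on both control 1 week arrays and FOXO 1 week replicate 2. Antioxidant and detoxification did not pass without FOXO 1 week replicate 1 (0.082). Of the single genes in this paragraph GstD5, TotC and Jon65Aiii passed in all 8 fits with an array left out. Lost were alphaTry without control 5 weeks replicate 1 (0.052), AttD and Fst without any 1 control array or FOXO 5 weeks replicate 1 (largest 0.0591 and 0.103), and MtnB, Drsl4 and CecB without any 1 array of the control groups or of FOXO 5 weeks (0.105, 0.126 and 0.125), CecB also without FOXO 1 week replicate 2.

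The last comparison sets the effects beside each other across 11982 genes, which are not independent replicates. The FOXO effects at 1 week and 5 weeks had a Pearson correlation of -0.545 and a Spearman correlation of -0.264, and 536 genes were called lower at 1 week and higher at 5 weeks, where 66.6 would be if the calls were independent. The age effects in control and FOXO hearts correlated at -0.429 (Spearman -0.056), and 629 genes fell in control and rose in FOXO hearts, where 96.3 would be. Genes that fell with age in control also fell in FOXO hearts at 1 week: the correlation was 0.692 (Spearman 0.493) and 558 genes were called both ways. Simulated unchanged groups gave 0.499 for that pair, since both effects share the control 1 week arrays, and the covariance was 0.405 against a simulated 0.0658. With the FOXO effect at 5 weeks the age effect in control correlated at -0.680 (Spearman -0.441), against -0.502 in simulations, and the covariance was -0.581 against -0.0662. Neither of these Spearman correlations was larger in size than the simulated Pearson correlation of its pair, but no Spearman correlation was simulated. The simulated groups also had 1 common spread per gene. In the data the SD of the replicate difference was 0.83 in FOXO 1 week and 0.22 in control 1 week. The simulated values therefore cannot decide how much of either correlation comes from the shared arrays. Without FOXO 1 week replicate 1 the correlations of the FOXO effects and of the age effects were -0.601 and -0.367, and without FOXO 1 week replicate 2 the FOXO effects correlated at -0.422.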

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

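The tests of male flies in FOXO 5 weeks, of FOXO itself, of the age of the flies, of fat body tissue, of RNA quality and of an exchanged label as the source of ovary transcripts were chosen only after the result was seen, the test of male germline RNA was divided by group after it was seen, and the marker lists were written after the data were first seen. The test lists of testis-specific copies and of other ovary transcripts, and the genes Cyp4d21, sxe2 and fit, which replaced genes without a probe set, were chosen before their values were looked at.

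The FOXO effect differed between the ages, by a test of the difference itself, for 1766 of 18769 probe sets and for 53 of the 95 genes named in the comparisons of pairs of groups. These 95 were picked for large changes on the same arrays, so a higher share among them follows in part from the choice. The effect at 5 weeks was above that at 1 week by 10.41 on the log2 scale for CG14294, 9.86 for CG2127, 9.69 for CG8517, 9.65 for CG18449 and 9.58 for CG3330, and by 6.49 for Atg8b, 6.48 for Hsp60B, 5.15 for Vha68-3 and 1.48 for daw. The difference was -7.84 for Muc11A, -4.67 for mat, -4.30 for Ag5r, -4.06 for CG34296 and -3.57 for Pvf1. The call for Pvf1 was lost without any 1 array of the control groups or of FOXO 5 weeks (largest adjusted p = 0.156).

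Of the 1366 rises in this difference 714 were left without probe sets that follow a marker list, and the late spermatogenesis transcripts had a mean 2.83 higher in control 1 week and 3.80 higher in FOXO 5 weeks than in control 5 weeks. Age alone was argued against, since the 5 weeks groups share an age and differed by 3.80. FOXO cannot account for the first part, since that group is the control cross. Male flies in place of all females were argued against for FOXO 5 weeks, where the female-specific transcripts lay 0.16 above control 5 weeks. That test cannot exclude some male flies among the females there, since the transcripts of the females would remain high. RNA of male germline cells may contribute in FOXO 5 weeks: 30 testis-specific copies of broadly used genes, 4 of them above the array median on all arrays and 1 in another list, had a median 3.002 higher there, with 25 higher and 1 lower past the test, while Mst84Dc, with the highest signal of the late list there, had 12.23 and 12.27 against 8.13 and 8.12 in control 5 weeks. Of 7 Y-linked fertility genes, low in signal, 2 were higher there (median 0.43). Other male lists moved little or the other way: 1 of 9 regulators of spermatocyte transcription was higher (median 0.16), and 0 of 19 accessory gland proteins (median -0.39). In control 1 week the copies had a median 0.57 higher, with 7 higher and 1 lower, between the bounds set beforehand. Mst84Dc had 12.16 and 12.30 there, near its values in FOXO 5 weeks. By the rule set for the copies, RNA of male germline cells in control 1 week stays open. An effect of FOXO on these genes in FOXO 5 weeks (3.80) cannot be told apart from such RNA because both would come with the group; suction, the removal step per the labels, took off fat and pericardial cells.

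The 5 female-specific transcripts were low on both control 1 week arrays and on FOXO 1 week replicate 2, with means of 6.86, 6.83 and 6.61 against 13.09 to 13.34 elsewhere. Age alone was argued against, since the FOXO 1 week arrays share an age and differed by 6.73, and so was more fat body and oenocyte tissue on the other 5 arrays, because markers of that tissue without sex-specific expression differed by 0.022. All 11 of these markers lay above the array median on all arrays (Cyp4g1, with the highest signal, between 13.70 and 13.80), and suction of fat cells was the removal step per the labels. Male flies on the 3 arrays may be a source: the mean of Cyp4d21 and sxe2, transcripts higher in males, was at least 1.01 higher there than in control 5 weeks and on FOXO 1 week replicate 1, but fit, higher in females, was lower by a size under the bound (-0.50), so this cannot be told apart from other causes. Male accessory gland transcripts, not part of that test, had medians of 5.85, 5.24 and 5.32 on the 3 arrays and at most 4.46 elsewhere. Their means lay closer, at 5.41 on FOXO 1 week replicate 2 and 5.35 on control 5 weeks replicate 1. No biological explanation other than age was tested.

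Oocyte and nurse cell transcripts were high on FOXO 1 week replicate 1 alone. As their source, an exchange of its label with an array of another group was argued against, since the median of 34 other ovary transcripts lay at least 4.71 above that on any such array, and so was lower RNA quality, since the 3' minus 5' signal of control genes was 1.13, within the 0.957 to 1.55 of the other 7 arrays. RNA of the ovary may be the source: the 34 transcripts, 12 of them above the array median on all arrays and 0 in another list, had a median 4.31 higher than on FOXO 1 week replicate 2, and osk and yl, with the highest signal of the first list, had 12.41 and 12.40 against 4.32 and 5.65, while grk of the same list had 10.26 against 10.15. Whether the label is wrong apart from these transcripts stays open, since the correlation test set for it beforehand decided nothing: the array had 0.963 with its own replicate and, as its highest, with an array of another group. How far suction, the removal step per the labels, would take off ovary tissue stays open too, and no biological explanation was tested, since the design names none for 1 array.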

How the results depend on the processing

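The marker covariates, the count without probe sets that follow a marker list and the fit of 6 arrays without the FOXO 1 week group were chosen only after the result was seen. For each result below that moved, the cause was not tested, unless fewer probe sets or arrays were used or the step itself gives it.

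Counts of probe sets that moved by more than 1.5 times were these. Centred array medians gave 9573 for FOXO at 5 weeks, 9415 for age in FOXO, 8997 for the difference of effects, and over both 7 for FOXO and 121 for age. Centring shifts all log2 fold changes of a comparison by the same amount. For FOXO at 5 weeks their median went from -0.16 to -0.52, and 8238 of the 9573 were lower. Without dim probe sets the first 3 were 1152, 1865 and 1082. With arrayWeights the counts were 3342 for FOXO at 5 weeks, 3681 for age in control, 1755 for age in FOXO, and over both 142 for FOXO and 2463 for age. From only the 4 arrays of the compared groups they were 274 for FOXO at 1 week, 3380 at 5 weeks, 3627 for age in control and 1421 in FOXO. Without the probe sets that follow a marker list, chosen by their correlation over the same arrays so that a lower count follows from the choice, they were 290, 1281, 687 for age in control and 1061 for the difference. The 6 arrays gave 4278 for FOXO at 5 weeks and 3279 for age in control, and an adjusted p under 0.1 gave 4409 for age in FOXO and 870 over both. For FOXO and age over both, the average of 2 contrasts gave 1168 and 2165 and marker covariates gave 1123 and 4393. The average comes from the model with 1 mean per group, whose spread does not hold the difference of effects. FOXO over both was 13 with quantile normalization, 4 with trend and robust and 10 with 1 probe set per gene.

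With 1 array left out, its group keeps 1 array that is assumed to vary like the other groups. The counts then lay between 400 and 5377 for FOXO at 1 week, 1368 and 4278 at 5 weeks, 605 and 3279 for age in control, 1670 and 6698 for age in FOXO, 1322 and 5541 for the difference, 1 and 154 for FOXO over both and 56 and 945 for age over both. The lowest followed arrays of the control or FOXO 5 weeks groups and the highest followed FOXO 1 week arrays.

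Of the gene lists, 12 of 155 tests passed by camera, between 12 and 27 with an array left out, 0 with an estimated correlation and 14 with fry. Over both, 24 of 62 passed, between 20 and 27 with an array left out, 0 with an estimated correlation and 1 with fry. Without FOXO 1 week replicate 1 female germline and eggshell markers turned upwards with age over both genotypes (adjusted p = 0.922, against 0.00839 without FOXO 1 week replicate 2 as the lowest of these fits).

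With a replicate block, the counts were 1 for FOXO and 213 for age over both, and 743, 1898, 1229, 2735 and 1685 in the order of the other comparisons. Whether the replicate numbers pair the arrays stays open: 2 of 6 group pairs had replicate differences that correlated over 0.1, with all 6 between 0.0133 and 0.332. The highest was that of control 5 weeks with FOXO 5 weeks.

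With an array left out foxo lay between -0.257 and 0.15 for FOXO at 1 week, turned without FOXO 1 week replicate 1, between -0.301 and 0.107 for the difference, turned without FOXO 1 week replicate 2, and between -0.634 and -0.227 for age in FOXO, where it passed without FOXO 1 week replicate 1, and RpS5b lay between 2.382 and a value turned to -0.078 for FOXO over both without FOXO 1 week replicate 1. Of 196 called values of named genes, 179 passed with quantile normalization, 177 with trend and robust, and 120 to 189 with an array left out, and 0 turned sign. With an array left out, the FOXO effects at the 2 ages correlated between -0.601 and -0.422, the age effects between -0.436 and -0.367, and the age effect in control between 0.564 and 0.709 with the FOXO effect at 1 week and between -0.688 and -0.663 with that at 5 weeks, the last -0.704 without dim probe sets.

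Centred medians moved the median of all probe sets to 0.18 for FOXO at 1 week, 0.21 for age in control, -0.15 for FOXO over both and -0.14 for age over both, from 0.04, 0.05, -0.04 and -0.05. Signal over background was not analysed here, and the number of arrays limits the precision.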

Other observations

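The counts of list genes that lie above the array median were made only after the result was seen, and the splits of the arrays were planned.

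Markers of pericardial nephrocytes, which flank the heart, had medians between 10.28 and 11.21 on the 8 arrays, and markers of hemocytes, the fly's blood cells, between 10.40 and 11.17. Neither list passed camera in any comparison. Over both ages their medians were -0.11 (adjusted p = 0.181) and -0.12 (adjusted p = 0.158) for FOXO, and over both genotypes 0.14 and 0.06 for age. Oenocyte markers lay between 12.25 and 13.12, flight muscle markers between 7.58 and 8.57 and neuron markers between 6.08 and 6.84.

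Of the 29 late spermatogenesis transcripts 6 lay above the array median on all 8 arrays, and so did 2 of 5 female-specific, 3 of 9 oocyte and nurse cell, 1 of 13 eggshell, 2 of 19 accessory gland, 1 of 9 spermatocyte and 0 of 7 Y-linked transcripts. All oocyte, eggshell and female-specific genes were also in another list.

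Splits of the 8 arrays into 4 and 4 were counted for the comparisons over both, 34 that could be fitted, the real one included. For the FOXO effect 2 splits gave as many probe sets as the real 20, with 882 in the highest other, and 17 gave as many gene lists as the real 8, with 16 in the highest other. For age 2 splits gave as many probe sets as the real 352, with 865 in the highest other, and 3 gave as many gene lists as the real 16, with 18 in the highest other. Chance could not be excluded in any of the 4. The split with 882 or 865 sets control 1 week with FOXO 5 weeks against the rest and points to a structure of the samples, in the direction of the difference of effects by design. All further splits gave 0 probe sets.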
